A study of Mus musculus with 18 samples.

How the data were processed

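Total RNA of RAW264.7 cells was extracted with Trizol, purified on RNeasy columns, labelled with biotin by the one-cycle protocol and hybridized to Affymetrix Mouse Genome 430 2.0 arrays. Treatments were applied in the dark, followed by 30 min of ambient light. The 18 arrays formed 6 groups of 3: vehicle, fraction and 4-compound mixture, each with and without LPS. The values deposited by the authors were linear signal intensities of 45101 probe sets from MAS5, whose version was not given in the sources used here. Every array had a 2% trimmed mean of 500.0, the target of the scaling, and array medians between 52.1 and 66.8. Detection calls and raw scans were not analysed here.

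Control probe sets (64) were left out. Of the others, 34945 carried 1 gene symbol, 932 several and 9160 none. Symbols were matched to a RefSeq table by Entrez ID for 34741 probe sets, and 204 symbols were kept as annotated. Intensities under 1 were set to 1 (0.823% of values) and taken to log2. A probe set was kept if it reached the array median on at least 3 of the 18 arrays, which left 25612 probe sets, 21553 of them with 1 symbol. The brightest probe set stood for each of 11547 genes, 5575 of which had more than 1 kept probe set. For 1220 genes the probe set was of a kind open to cross-hybridization, among them Trib3, Socs3, Fcgr2b, Angptl4, Hpgd and Nme1, and Hspa1b has a near-identical copy in Hspa1a. Genes whose probe sets were called in both directions numbered 9 of 4111 for LPS in vehicle cells, 36 of 4023 for the fraction without and 51 of 3317 with LPS.

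One linear model with 6 group means was fitted with limma 3.58.1 under R 4.3.3 (eBayes with an intensity trend, 12 residual degrees of freedom). The 11 contrasts were LPS against none within each treatment, fraction and mixture against vehicle and against each other at each LPS state, and the interactions of fraction and mixture with LPS. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Gene lists were tested with camera (preset correlation 0.01) and adjusted over 21 lists, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. Of 78 list tests past the threshold, median, mean and test differed in sign in 1 (JAK-STAT for LPS in mixture-treated cells), and of the 153 others in 49.

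The lists were cytokines and chemokines, prostaglandin, leukotriene and nitric oxide mediators, type I interferon response, feedback inhibitors, Toll-like receptor and NF-kB components, JAK-STAT, NRF2, aryl hydrocarbon receptor, cholesterol synthesis, LXR targets, unfolded protein and integrated stress response, heat shock, cell cycle, glycolysis and hypoxia, apoptosis and p53 targets, macrophage identity, alternative activation, lysosome, antigen presentation, extracellular matrix, and markers of other cell types, of which 8 of 28 were measured.

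The comparisons, lists, thresholds, most alternatives and the rule for named genes were set before the data were examined. That rule took genes past the threshold whose 3 arrays in one group all lay above those of the other, the 10 with the largest rise and the 10 with the largest fall (12 each for LPS in vehicle cells and for the fraction or the mixture against vehicle with LPS), 5 each for interactions, up to 4 members per list, and Ptgs2, Tnf, Il1b, Il6, Nos2, Socs3, Hmox1 and Cyp1a1 throughout. Where fewer than 5 genes passed, the 5 with the smallest p were named. Cyp1a1 was not among the tested genes. Not every gene so chosen is given in the text. Where a group lay under its array median, the fold was computed against the array median and given as a lower bound, and with both groups under it only the log2 difference was given, without a fold. This treatment of folds was chosen after seeing the data, as were the alternatives that leave out the 6 arrays numbered 1, take the mixture arrays as controls, or set low signals to the array median.

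Gene tests were repeated with a replicate block, quantile normalization, median centring, log2 of the value plus 32 and no filter. Others were a 75th percentile filter, no eBayes trend, every probe set, only compared arrays, a 1.5-fold minimum and each array left out in turn. Tests of lists and LPS-responsive sets were repeated with an estimated correlation, fry, the block, quantile normalization, the 75th percentile filter and fewer arrays. The correlation of effects was repeated with quantile normalization, the value plus 32, the 75th percentile filter and each array left out. The labels do not state what a replicate number shares, so the arrays were not treated as paired. For effects that shared vehicle arrays, 100 simulations of unchanged groups gave the correlation and covariance due to shared controls. Means of LPS-responsive sets were compared by exact permutation, whose smallest p for 3 against 3 is 0.1.

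The design was tested on simulated data with 200 changed genes in 20 simulations. Log2 changes of 0.5, 1 and 2 were found in 41.9%, 74.9% and 89.9% of cases for the mixture plus LPS and in 16.3%, 64.4% and 83.6% for the fraction interaction. The share of false calls lay between 4.03% and 6.11%. A shift planted in a list was found in 20 of 20 simulations. The simulated values varied independently between genes and between arrays. These checks therefore do not cover correlated genes or shifts shared by a replicate number. Ratios of 3' to 5' probe sets were 0.821 to 0.863 for Gapdh, and spiked-in bioB gave signals of 310 to 483.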

Results

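RAW264.7 mouse macrophages were treated for 8 h with solvent (0.1% DMSO, called vehicle below), with a sub-fraction of Hypericum perforatum (St John's wort) at 10 ug/mL, or with a mixture of 4 compounds. The mixture held pseudohypericin at 0.03 uM, chlorogenic acid at 0.2 uM, amentoflavone at 0.07 uM and quercetin at 0.08 uM. Each treatment was given with or without 10 ug/mL lipopolysaccharide (LPS), a bacterial ligand of Toll-like receptor 4. The 6 groups had 3 arrays each, so every comparison of 1 group with another set 3 arrays against 3. The interactions with LPS used the arrays of 4 groups, and 11547 genes were tested. Changes are given as log2 differences of group means ± standard error. The labels do not state whether the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical in part. Correlations between arrays of one group lay between 0.970 and 0.979, and the first principal component held 37.3% of the variance.

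In vehicle-treated cells, LPS raised the genes of the secreted mediators Il1b, Csf3, Ccl5 and Lif. Il1b, the gene of interleukin 1 beta, rose 158-fold (7.30 ± 0.21, adjusted p = 9.7e-15, n = 3 per group), from a mean intensity of 82.5 to 13017. Csf3, which encodes a growth factor of neutrophils, rose 166-fold (7.38 ± 0.32, adjusted p = 5.7e-12), the chemokine gene Ccl5 52.8-fold (5.72 ± 0.18) and the cytokine gene Lif 63.1-fold (5.98 ± 0.22). Il6, Il1a, Ccl22 and Csf2 lay under the array median without LPS and rose at least 66.1-fold, 16.005-fold, 22.0-fold and 12.6-fold. Among the genes that fell were Cdc6, a replication licensing factor (5.99-fold lower, -2.58 ± 0.17, adjusted p = 1.1e-09), and Ung, a uracil DNA glycosylase (6.73-fold lower, -2.75 ± 0.22).

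Of the 11547 genes, 3680 passed, 1161 higher and 2519 lower with LPS, and 410 in each direction changed by at least 2-fold. The split of directions depended on the scaling: after median centring, which moved the median of all genes by 0.19, 2366 genes were higher and 1351 lower. In this response 2512 genes were called both ways with the same sign and 0 with the opposite sign. Among inflammatory cytokines and chemokines, 25 of 26 measured members rose and 0 fell (25 and 0 adjusted over the list alone, camera adjusted p = 3.3e-29). Of the feedback inhibitors of inflammatory signalling, 24 of 27 rose (25 over the list alone, adjusted p = 9.4e-29), including Socs3, an inhibitor of cytokine receptor signalling (5.15 ± 0.24, adjusted p = 1.5e-11), and Dusp5 (3.87 ± 0.20). Among type I interferon response genes, 31 of 35 rose and 0 fell (33 over the list alone, adjusted p = 1.1e-23), with Gbp3 at 3.33 ± 0.42 and Cxcl11 at 3.30 ± 0.37. The interferon list had an adjusted p of 0.071 with an estimated correlation.

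Of the cell cycle and DNA replication genes, 33 of 34 fell and 0 rose with LPS (33 over the list alone), 28 after median centring, with Tk1 at -2.22 ± 0.17 and Ccne2 at -2.10 ± 0.28. The list had a camera adjusted p of 1.7e-17 and an adjusted p of 0.070 with an estimated correlation. In the Toll-like receptor and NF-kB list, 17 of 33 rose and 3 fell (17 and 4 over the list alone, adjusted p = 9.7e-08), with the NF-kB kinase gene Ikbke at 2.57 ± 0.17 and Rel at 1.88 ± 0.11. Among apoptosis and p53 targets, 12 of 24 rose and 5 fell, the same counts over the list alone (adjusted p = 1.7e-05), with the death receptor gene Fas at 4.03 ± 0.19. In the extracellular matrix and adhesion list, 11 of 19 rose and 2 fell (13 and 2 over the list alone, adjusted p = 6.9e-07), and the protease inhibitor gene Timp1 rose at least 5.84-fold. Of the antigen presentation genes, 10 of 19 rose and 0 fell, also over the list alone (adjusted p = 5.2e-08, 0.071 as an adjusted p with an estimated correlation). The costimulatory genes Cd83 and Cd40 were at 3.49 ± 0.16 and 3.09 ± 0.17.

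Of the macrophage identity genes, 12 of 21 rose and 1 fell (14 and 1 over the list alone, adjusted p = 2.6e-06), 18 and 1 after median centring. The list had an adjusted p of 0.071 with an estimated correlation, with Itgam at 1.34 ± 0.16 and the transcription factor gene Cebpa at -1.30 ± 0.12. In the unfolded protein and integrated stress response list, 10 of 23 rose and 2 fell (10 and 3 over the list alone, adjusted p = 9.8e-04, 0.21 as an adjusted p with an estimated correlation). Of the glycolysis and hypoxia genes 6 of 20 rose and 1 fell (7 and 1, adjusted p = 0.011, 0.45 as an adjusted p with an estimated correlation), and 12 and 1 after median centring. In the mediator list 8 of 18 prostaglandin, leukotriene and nitric oxide genes rose and 3 fell (8 and 5, adjusted p = 0.017, 0.19 as an adjusted p with an estimated correlation). Ptgs2, the inducible cyclooxygenase gene, rose 2.75 ± 0.17 (adjusted p = 7.4e-10) and Nos2, the inducible nitric oxide synthase gene, 2.99 ± 0.56 (adjusted p = 3.7e-04). Tnf rose 1.62 ± 0.13 (adjusted p = 2.7e-08). Hmox1, the heme oxygenase gene, was at -0.04 ± 0.14 (adjusted p = 0.84).

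The other lists did not pass as wholes in the LPS response of vehicle cells. JAK-STAT genes had 9 of 27 higher and 6 lower (9 and 9 over the list alone, adjusted p = 0.13), and 11 and 4 after median centring. NRF2 genes had 6 of 25 higher and 4 lower (7 and 4, 0.15), and 5 and 7 after quantile normalization. LXR targets had 5 of 17 higher and 4 lower, also over the list alone (0.29), 5 and 1 after median centring, and 4 and 2 after quantile normalization. Cholesterol synthesis had 1 of 20 higher and 1 lower (0 and 1, 0.89), aryl hydrocarbon receptor genes 2 of 8 higher (1, 0.32), and alternative activation genes 2 of 8 higher and 2 lower (3 and 2, 0.13). Heat shock genes had 1 of 18 higher and 2 lower (1 and 1, 0.19), and 8 and 0 after median centring. Lysosome genes had 4 of 21 higher and 2 lower, also over the list alone (0.13), 11 and 1 after median centring, and 2 and 3 after quantile normalization. Of 8 measured markers of other cell types, 1 rose, the epithelial gene Epcam (at least 2.15-fold, 1.75 ± 0.46, adjusted p = 0.0060), with a camera adjusted p of 0.10.

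**Figure D1:**
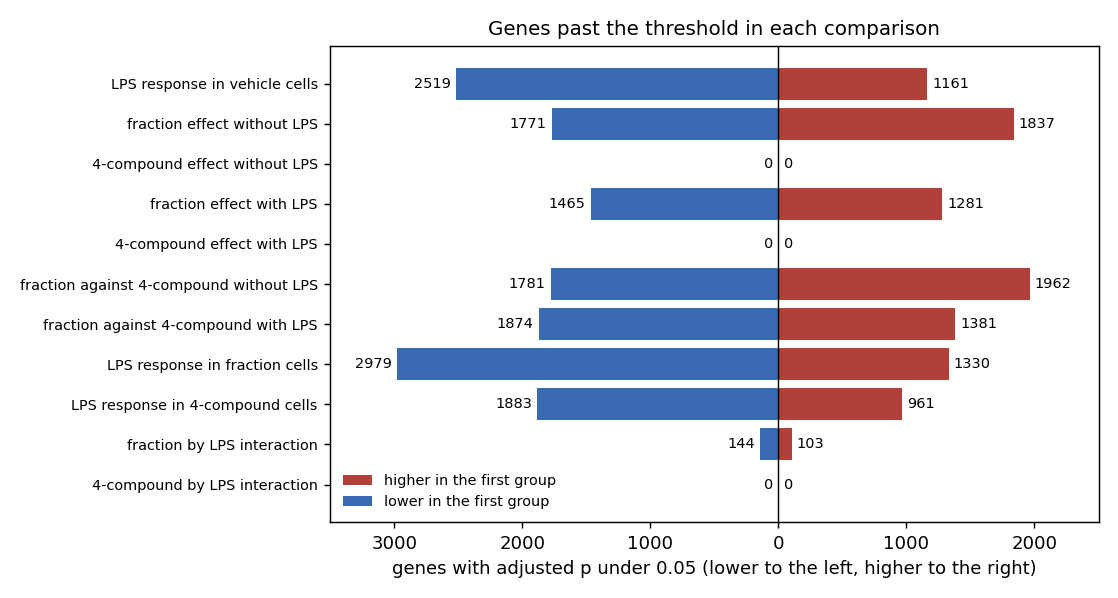
Number of genes with a higher or a lower mean at an adjusted p < 0.05 (limma) in each of the 11 comparisons, with bars to the right for higher and to the left for lower. Each comparison used 3 arrays per group and 11547 genes, with 3680 genes for LPS in vehicle cells, 3608 for the fraction and 0 for the 4-compound mixture without LPS.

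Without LPS, the fraction raised the stress genes Trib3 and Ddit3 and lowered Hspa1b, Cxcl10 and Ung. Trib3, a pseudokinase gene induced by amino acid shortage and endoplasmic reticulum stress, rose 26.6-fold (4.73 ± 0.16, adjusted p = 4.0e-13, n = 3 per group), from a mean intensity of 193 to 5134. Ddit3, which encodes the stress transcription factor CHOP, rose 21.5-fold (4.42 ± 0.23, adjusted p = 6.2e-11), Slc40a1, the iron exporter gene, 18.6-fold (4.22 ± 0.46, from a mean of 55.8 close to the array medians) and Fcgr2b, an inhibitory Fc receptor gene, 14.1-fold (3.82 ± 0.23). Aqp9, a channel for glycerol and water, rose at least 9.43-fold. Hspa1b, an inducible heat shock protein gene, fell 15.0-fold (-3.91 ± 0.17, adjusted p = 8.3e-12), the chemokine gene Cxcl10 6.94-fold (-2.79 ± 0.18), Ung 7.00-fold (-2.81 ± 0.22) and Ifit1, an interferon-induced gene, 5.86-fold (-2.55 ± 0.23).

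The fraction changed 3608 genes without LPS, 1837 higher and 1771 lower, of which 389 and 195 by at least 2-fold. After median centring 1747 were higher and 1862 lower, so the direction of the larger share depended on the scaling. In 42.9% of genes the 3 fraction arrays did not overlap the 3 vehicle arrays, where chance gives 10%. Of the type I interferon response genes, 29 of 35 fell and 0 rose (30 over the list alone, camera adjusted p = 4.4e-14, 0.23 as an adjusted p with an estimated correlation), including Cmpk2 (-2.33 ± 0.35, adjusted p = 4.3e-05). Of the cholesterol synthesis genes, 16 of 20 fell and 0 rose, also over the list alone (adjusted p = 1.4e-11, 0.13 as an adjusted p with an estimated correlation). Insig1, a regulator of sterol sensing, was at -2.27 ± 0.17 and Hmgcs1, an early enzyme gene of the pathway, at -1.49 ± 0.13. Among cell cycle genes 19 of 34 fell and 0 rose (23 over the list alone, adjusted p = 1.1e-08, 0.23 as an adjusted p with an estimated correlation), with Ccne2 at -2.15 ± 0.28 and Rrm2 at -1.38 ± 0.14.

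Of the unfolded protein and integrated stress response genes, 12 of 23 rose and 2 fell with the fraction without LPS, also over the list alone (adjusted p = 9.3e-07, 0.23 as an adjusted p with an estimated correlation). Chac1, a glutathione-degrading enzyme gene, was at 2.62 ± 0.22 and Ppp1r15a at 2.49 ± 0.18. Of the NRF2 antioxidant genes, 8 of 25 rose and 1 fell, also over the list alone (adjusted p = 0.0047, 0.23 as an adjusted p with an estimated correlation), with the cystine transporter gene Slc7a11 at 1.99 ± 0.11. Of the prostaglandin, leukotriene and nitric oxide genes, 8 of 18 rose and 1 fell (9 and 1 over the list alone, adjusted p = 0.0084, 0.23 as an adjusted p with an estimated correlation). The prostaglandin E2 receptor gene Ptger2 rose at least 5.79-fold, the prostacyclin receptor gene Ptgir was at 2.26 ± 0.36, and Gch1, an enzyme gene of tetrahydrobiopterin synthesis, at 1.86 ± 0.13. Of the lysosome genes 7 of 21 rose and 1 fell, also over the list alone (adjusted p = 0.013, 0.36 as an adjusted p with an estimated correlation), with Npc1, a cholesterol export gene, at 0.99 ± 0.17. Of the heat shock genes 7 of 18 fell and 2 rose, also over the list alone (adjusted p = 0.019, 0.23 as an adjusted p with an estimated correlation), with the co-chaperone gene Dnajb1 at -0.80 ± 0.11.

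The remaining lists did not pass as wholes with the fraction without LPS, although single members did. Apoptosis and p53 targets had 11 of 24 higher and 3 lower, also over the list alone (camera adjusted p = 0.065), with the growth arrest gene Gadd45a at 3.63 ± 0.27 and Bbc3 at 1.93 ± 0.18. LXR targets had 2 of 17 higher and 5 lower (2 and 7, 0.065), with the lipid droplet gene Plin2 at 2.00 ± 0.23 and Fasn at -1.26 ± 0.087. Feedback inhibitors had 7 of 27 higher and 3 lower, also over the list alone (0.23), with Atf3 at 3.18 ± 0.24 and Socs3 3.58-fold lower (-1.84 ± 0.24, adjusted p = 8.1e-06). Cytokines had 4 of 26 higher and 3 lower (3 and 3, 0.82), and 3 and 5 after quantile normalization, with the chemokine gene Cxcl2 at 1.97 ± 0.20. Alternative activation had 2 of 8 higher (also over the list alone, 0.10), with Klf4 at 3.62 ± 0.20.

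Toll-like receptor and NF-kB genes had 6 of 33 higher and 3 lower with the fraction without LPS (adjusted p = 0.88), with Tlr4, the LPS receptor gene, at 1.18 ± 0.11. JAK-STAT had 4 of 27 higher and 5 lower (0.88), macrophage identity 3 of 21 higher and 1 lower (0.44) and antigen presentation 4 of 19 higher and 1 lower (0.82), with the same counts over each list alone. Glycolysis and hypoxia had 3 of 20 higher and 3 lower (3 and 4 over the list alone, 1.00), and extracellular matrix genes 1 of 19 higher and 2 lower (0 and 2, 0.55). Aryl hydrocarbon receptor genes and markers of other cell types had 0 members past the threshold (0.82 for both). Ptgs2 rose 1.68-fold (0.75 ± 0.17, adjusted p = 0.0025, against 0.41 and 0.063 without the 6 arrays numbered 1, and an adjusted p from 2.5e-04 over the alternatives). Tnf fell 1.57-fold (-0.65 ± 0.13, adjusted p = 0.0011), and Hmox1 rose 3.46-fold (1.79 ± 0.14, adjusted p = 1.7e-08). Il1b was at -0.50 ± 0.21 (adjusted p = 0.075) and Nos2 at 0.66 ± 0.56 (0.41). Il6 was under the array median in both groups at 1.52 ± 0.56 (adjusted p = 0.047). Without replicate 3 of the vehicle group Il6 was at 0.71 (0.314), and without replicate 1, 2 or 3 of the fraction group the adjusted p was 0.081, 0.131 and 0.072 (0.021 to 0.314 over all alternatives).

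**Figure D2:**
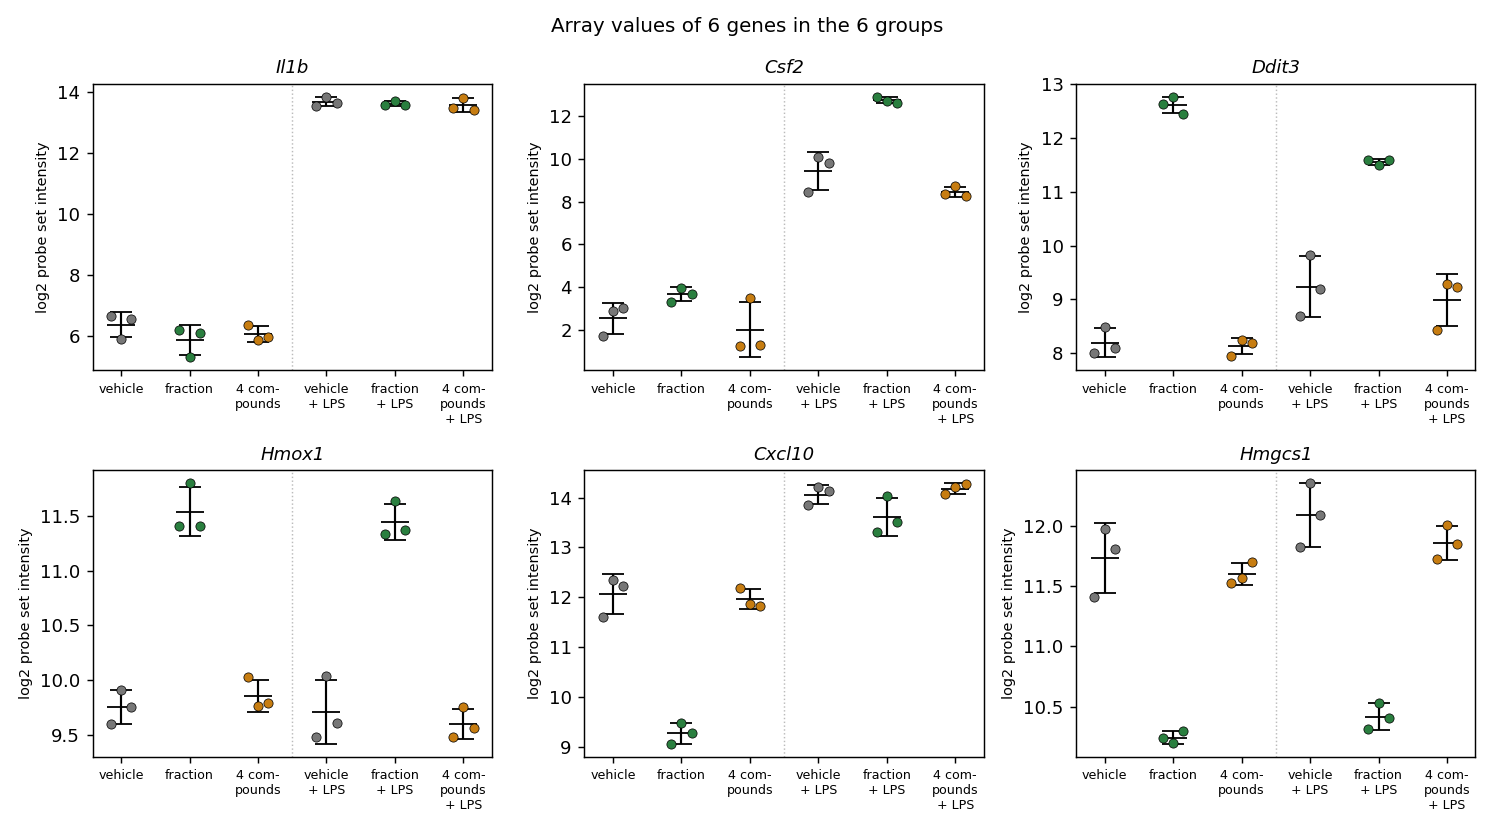
Log2 intensity of single genes in the 6 groups, with a point for each array and the mean ± SD of n = 3 arrays. Ddit3 means rose from 292 to 6275 with the fraction without LPS, while Cxcl10 means fell from 4281 to 617.

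In LPS-stimulated cells, the fraction raised Csf2, Lcn2, Aqp9 and Trib3 and lowered Scd2 and Htr1b against vehicle plus LPS. Csf2, the gene of granulocyte-macrophage colony-stimulating factor, was 9.89-fold higher (3.31 ± 0.51, adjusted p = 9.6e-05, n = 3 per group), from a mean intensity of 698 to 6897. Lcn2, which encodes an iron-scavenging protein, was 7.97-fold higher (2.99 ± 0.45), Aqp9 11.4-fold (3.51 ± 0.31) and Trib3 9.78-fold (3.29 ± 0.16, adjusted p = 1.3e-10). The chemokine gene Ccl20 was higher by at least 4.31-fold (adjusted p = 0.0068, 0.064 without the 6 arrays numbered 1, from 6.9e-08 over the alternatives). Scd2, a fatty acid desaturase gene, was 5.18-fold lower (-2.37 ± 0.22, adjusted p = 2.7e-07) and the serotonin receptor gene Htr1b 4.99-fold lower (-2.32 ± 0.29).

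With LPS, 2746 genes differed between fraction and vehicle, 1281 higher and 1465 lower, and 244 and 147 by at least 2-fold. Without replicate 1 of vehicle plus LPS, 1225 were higher and 1190 lower. In 36.1% of genes the groups did not overlap, where chance gives 10%. Cholesterol synthesis genes fell in 17 of 20 cases with 0 higher (18 over the list alone, camera adjusted p = 7.5e-16, 0.040 as an adjusted p with an estimated correlation). Stard4 was at -1.76 ± 0.14, Hmgcs1 at -1.67 ± 0.13 and Sqle at -1.40 ± 0.12. Of the unfolded protein and integrated stress response genes 12 of 23 rose and 2 fell, also over the list alone (adjusted p = 5.4e-06, 0.28 as an adjusted p with an estimated correlation), with Ddit3 at 2.32 ± 0.23 and Sesn2 at 1.51 ± 0.27. Of the cell cycle genes 20 of 34 fell and 3 rose (22 and 3 over the list alone, adjusted p = 1.3e-06, 0.48 as an adjusted p with an estimated correlation), with Plk1 at -0.86 ± 0.12. Of the NRF2 genes 9 of 25 rose and 2 fell (10 and 2, adjusted p = 0.0011, 0.28 as an adjusted p with an estimated correlation), with Slc7a11 at 1.10 ± 0.11.

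Of the cytokines and chemokines, 6 of 26 rose and 0 fell with the fraction plus LPS (7 over the list alone, adjusted p = 0.0093, 0.48 as an adjusted p with an estimated correlation), including Il23a at 2.22 ± 0.37. Il6 was 3.33-fold higher (1.74 ± 0.56, adjusted p = 0.030). Without replicate 1 of the vehicle plus LPS group Il6 was at 1.16 (adjusted p = 0.167), and without replicate 1, 2 or 3 of fraction plus LPS the adjusted p was 0.066, 0.078 and 0.062 (3.6e-04 to 0.210 over all alternatives). Of the interferon response genes 4 of 35 fell and 0 rose, also over the list alone (adjusted p = 0.0017, 0.84 as an adjusted p with an estimated correlation), with Irgm1 at -0.99 ± 0.19 and Ifit1 at -0.97 ± 0.23. Hmox1 was 3.35-fold higher (1.74 ± 0.14, adjusted p = 5.6e-08), and Ptger4, a prostaglandin E2 receptor gene, was at -2.22 ± 0.13 (adjusted p = 1.2e-09). Ptgs2 was at 0.24 ± 0.17 (adjusted p = 0.35), Tnf at 0.37 ± 0.13 (0.054), Il1b at -0.06 ± 0.21 (0.87) and Nos2 at -0.02 ± 0.56 (0.99). In vehicle plus LPS the mean signals of Ptgs2 and Tnf were 22748 and 19820, where the highest of any gene was 32019. A ceiling of the signal may limit the differences of these bright genes in all comparisons with LPS, which was not tested. Socs3 was 1.81-fold lower (-0.86 ± 0.24, adjusted p = 0.012), with an adjusted p of 0.0501 without replicate 2 of vehicle plus LPS and 0.059 without replicate 3 of fraction plus LPS (from 0.0024 over the alternatives). The other 15 lists did not pass with camera, with adjusted p values of 0.12 for apoptosis and p53 targets and higher for the rest.

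The fraction had effects without and with LPS on shared genes, in comparisons that used separate arrays. Of the genes higher with the fraction, 923 were called in both, where 204 were expected if calls were independent, and of those lower 943, where 225 were expected. The comparisons shared the estimate of the spread per gene, which favours shared calls, so these expected counts may be too low. In the opposite direction, 10 genes were higher without and lower with LPS, and 13 the other way round.

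Without LPS, the 4-compound mixture changed 0 genes at an adjusted p < 0.05 with limma, while 565 genes (4.89%) had an unadjusted p < 0.05. The 5 genes with the smallest p did not pass: Klhl2 at -0.56 ± 0.11 (adjusted p = 0.546), and Rpl22 at 0.33 ± 0.073, Ccr1 at -2.40 ± 0.53, E530011L22Rik at -1.61 ± 0.37 and Sox4 at 2.501 ± 0.624 (adjusted p = 0.814 for each). Ptgs2 was at -0.23 ± 0.17, Tnf at -0.19 ± 0.13, Il1b at -0.30 ± 0.21, Il6 at 0.55 ± 0.56, Nos2 at -0.77 ± 0.56, Socs3 at -0.18 ± 0.24 and Hmox1 at 0.11 ± 0.14 (adjusted p = 0.999 for each, n = 3 per group). Ccr1 and Il6 lay under the array median in both groups and Nos2, E530011L22Rik and Sox4 in 1 of them, so the sizes of these differences rest on low signals. Of the 21 lists, heat shock passed with camera (higher, adjusted p = 0.0090), with 0 of its 18 members past the threshold over all genes and 2 higher over the list alone. The chaperone genes Dnaja1 and Hspd1 were at 0.34 ± 0.10 and 0.28 ± 0.077. Its adjusted p was 0.31 with an estimated correlation and 0.52 with fry. In the same arrays the actin 3' to 5' ratio was 0.061 ± 0.019 and the spike-in signal 0.29 ± 0.17 (log2) above vehicle.

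The groups did not overlap in 8.31% of genes, where chance gives 10%. The 95% confidence interval of the change lay within 2-fold in either direction for 82.4% of genes, with a median width to either side of 0.30. In simulated data of the same design, 74.4% of genes given a log2 change of 1 and 42.6% of those given 0.5 were found.

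In LPS-stimulated cells, the mixture also changed 0 genes with limma, with 934 genes (8.09%) at an unadjusted p < 0.05. The 5 genes with the smallest p were Map1s at -0.60 ± 0.10 (adjusted p = 0.115), Piga at -0.49 ± 0.10, Lrrc8c at 0.99 ± 0.21, Ssh2 at -0.39 ± 0.084 and Helb at -0.63 ± 0.14 (adjusted p = 0.476 for each, none past the threshold). Ptgs2 was at -0.06 ± 0.17 (adjusted p = 0.96), Tnf at 0.16 ± 0.13 (0.77), Il1b at -0.11 ± 0.21 (0.92), Il6 at -0.88 ± 0.56 (0.70), Nos2 at -0.30 ± 0.56, Socs3 at -0.15 ± 0.24 and Hmox1 at -0.11 ± 0.14 (0.87). By camera, 5 lists passed: cytokines (lower, adjusted p = 0.029), and prostaglandin and nitric oxide genes (lower), feedback inhibitors (lower), heat shock (higher) and cell cycle (higher), each with an adjusted p of 0.016. With an estimated correlation the adjusted p values were 0.83, 0.46, 0.89, 0.46 and 0.89, and with fry 0 lists passed. By camera 0 lists passed without replicate 3 of vehicle plus LPS, and 10 without its replicate 1. In the mixture plus LPS arrays the spike-in signal was 0.35 ± 0.11 (log2) above vehicle plus LPS. It was also higher in fraction plus LPS, with bioB at 433, 370 and 432 against 315, 330 and 332 in vehicle plus LPS. In the 5 lists that passed with all arrays, 0 members passed, over all genes or over the list alone. Members with values included Csf2 at -1.01 ± 0.51, Ptgir at -1.07 ± 0.36, the phosphatase gene Dusp1 at -0.95 ± 0.38 and Hspa8 at 0.26 ± 0.086, none past the threshold. In the macrophage identity list, 3 of 21 members were lower over the list alone (camera adjusted p = 0.15).

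A single array decided this count. Without replicate 1 of the vehicle plus LPS group, 191 genes passed with the mixture plus LPS, 91 higher and 100 lower, and leaving out any other array of these 2 groups gave 0. Among them, the acute phase gene Saa3 was at -2.28 ± 0.23 (adjusted p = 6.0e-05, against -1.53 with all arrays), Lcn2 at -1.95 ± 0.32 (0.0049), the anti-inflammatory cytokine gene Il10 at -1.95 ± 0.35 (0.0078) and Gpr155 at 1.81 ± 0.31. Of the 191 genes, 132 also passed for LPS in fraction-treated cells, and 122 of these (92.4%) changed against that response. The left-out array responded least to LPS in its group, at 21.8 on the first principal component against 41.3 and 38.8. Leaving it out therefore favours differences opposed to the LPS response. With all arrays, the groups did not overlap in 12.6% of genes (chance 10%), and for 81.0% of genes the 95% confidence interval lay within 2-fold.

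The genes that LPS raised or lowered at least 2-fold were also tested as sets, each chosen in the arm of the experiment that the test did not use. With the mixture plus LPS, the 436 raised genes had a median change of -0.13 and a mean of -0.18, 66.7% of them below 0 (camera p = 2.9e-07, p = 0.14 with an estimated correlation). Their mean log2 intensity per array was 9.36 ± 0.089 (SD) against 9.54 ± 0.25 in vehicle plus LPS (exact two-sided permutation p = 0.4, n = 3 per group). The 603 lowered genes had a median of 0.12 (camera p = 9.0e-04, 0.19 with an estimated correlation, exact p = 0.4). Without replicate 1 of vehicle plus LPS the means of the raised and lowered genes were -0.33 and 0.17, against -0.18 and 0.094 with all arrays. With the fraction plus LPS, the 340 raised genes had a median change of 0.11, with 65 higher and 34 lower (camera p = 0.025, 0.55 with an estimated correlation, exact p = 0.6). The 287 lowered genes had a median of -0.14, with 31 higher and 64 lower (camera p = 0.025, 0.40 with an estimated correlation, exact p = 0.5). These shifts depended on 1 array: without replicate 1 of vehicle plus LPS the means of the 2 sets were -0.010 and -0.012, against 0.15 and -0.12 with all arrays.

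**Figure D3:**
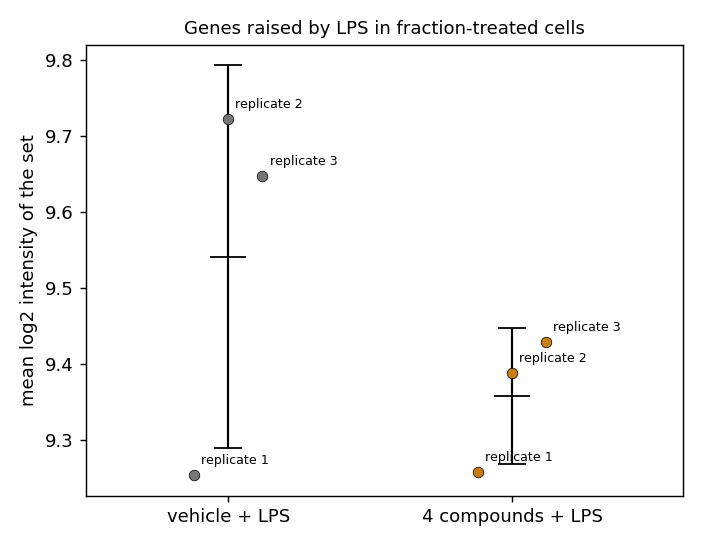
Mean log2 intensity of the genes raised at least 2-fold by LPS in fraction-treated cells, for vehicle plus LPS and the mixture plus LPS. Each point is 1 array, with the mean ± SD of n = 3 arrays. The 436 genes had a mean of 9.54 in vehicle plus LPS and 9.36 in the mixture plus LPS, with replicate 1 of vehicle plus LPS at 9.25.

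The fraction was compared with the mixture directly, although the concentrations of the 4 compounds in the fraction are not given in the labels, so the doses may differ. Without LPS, Trib3 was 33.9-fold higher with the fraction than with the mixture (5.08 ± 0.16, adjusted p = 1.1e-13, n = 3 per group), Ddit3 22.4-fold (4.49 ± 0.23), Fcgr2b 14.7-fold (3.87 ± 0.23) and Gadd45a 12.7-fold (3.66 ± 0.27). Hspa1b was 16.04-fold lower (-4.00 ± 0.17, adjusted p = 5.2e-12), Ifit1 7.27-fold (-2.86 ± 0.23) and Cxcl10 6.46-fold (-2.69 ± 0.18). Hmox1 was 3.21-fold higher (1.68 ± 0.14, adjusted p = 3.7e-08) and Ptgs2 1.98-fold higher (0.98 ± 0.17, adjusted p = 2.2e-04), and Socs3 was at -1.66 ± 0.24 (2.5e-05). Il6 was under the array median in both groups at 0.96 ± 0.56 (adjusted p = 0.21), Nos2 at 1.44 ± 0.56 (0.055) and Il1b at -0.20 ± 0.21 (0.51).

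Without LPS, 3743 genes differed between fraction and mixture, 1962 higher and 1781 lower, of which 434 and 205 by at least 2-fold. The larger share turned with the scaling, with 1676 higher and 2125 lower after median centring and 1820 and 1954 after quantile normalization. By camera 8 lists passed, with the adjusted p with an estimated correlation given second for each. Lower with the fraction were 27 of 35 interferon response genes (30 over the list alone, 5.3e-14, 0.21), 14 of 20 cholesterol synthesis genes (17, 4.9e-10, 0.099), and 20 of 34 cell cycle genes (21, 3.7e-09, 0.21). The same held for 9 of 18 heat shock genes with 1 higher (11 and 1, 5.0e-04, 0.099). Higher were 12 of 23 unfolded protein and integrated stress response genes with 3 lower (also over the list alone, 3.4e-06, 0.20) and 8 of 18 prostaglandin and nitric oxide genes with 1 lower (10 and 1, 0.0019, 0.20). So were 11 of 24 apoptosis and p53 targets with 2 lower (12 and 3, 0.030, 0.21) and 7 of 25 NRF2 genes with 2 lower (7 and 3, 0.037, 0.34). Tnf was lower with the fraction (-0.45 ± 0.13, adjusted p = 0.014). Its adjusted p was 0.063 without replicate 1 of the fraction or replicate 2 of the mixture and 0.101 without replicate 3 of the mixture (from 1.2e-04 over the alternatives).

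With LPS, Csf2 was 19.9-fold higher with the fraction than with the mixture (4.31 ± 0.51, adjusted p = 3.8e-06), Lcn2 18.03-fold (4.17 ± 0.45) and Trib3 11.6-fold (3.53 ± 0.16). Cth, an enzyme gene of cysteine synthesis, was 10.7-fold higher (3.41 ± 0.14, adjusted p = 1.0e-11). Lower were Nme1, 5.89-fold (-2.56 ± 0.24), Scd2, 5.36-fold (-2.42 ± 0.22) and Pmepa1, 5.24-fold (-2.39 ± 0.40). Il6 was 6.14-fold higher (2.62 ± 0.56, adjusted p = 0.0016), Hmox1 3.62-fold higher (1.85 ± 0.14, 2.0e-08) and Socs3 lower (-0.71 ± 0.24, 0.029). The Socs3 call was lost without replicate 1 or 3 of fraction plus LPS or any 1 array of mixture plus LPS, with adjusted p from 0.0505 to 0.116 (from 2.1e-04 over all alternatives). Ptgs2 was at 0.30 ± 0.17 (0.22), Tnf at 0.21 ± 0.13 (0.27), Il1b at 0.05 ± 0.21 (0.89) and Nos2 at 0.28 ± 0.56 (0.76). In total 3255 genes differed, 1381 higher and 1874 lower, while 336 were higher and 182 lower by at least 2-fold.

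By camera 7 lists passed between fraction and mixture with LPS, again with the adjusted p with an estimated correlation second. Cholesterol synthesis had 17 of 20 lower (18 over the list alone, 5.1e-14, 0.062), cell cycle 25 of 34 lower and 2 higher (28 and 3, 1.9e-08, 0.33) and interferon response 10 of 35 lower (also over the list alone, 0.0049, 0.78). The unfolded protein and integrated stress response list had 12 of 23 higher and 2 lower (12 and 3, 2.0e-06, 0.33), and cytokines had 8 of 26 higher (also over the list alone, 5.3e-04, 0.33). NRF2 had 9 of 25 higher and 3 lower (11 and 3, 0.0095, 0.33), and prostaglandin and nitric oxide genes 6 of 18 higher and 2 lower (also over the list alone, 0.032, 0.33).

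**Figure D4:**
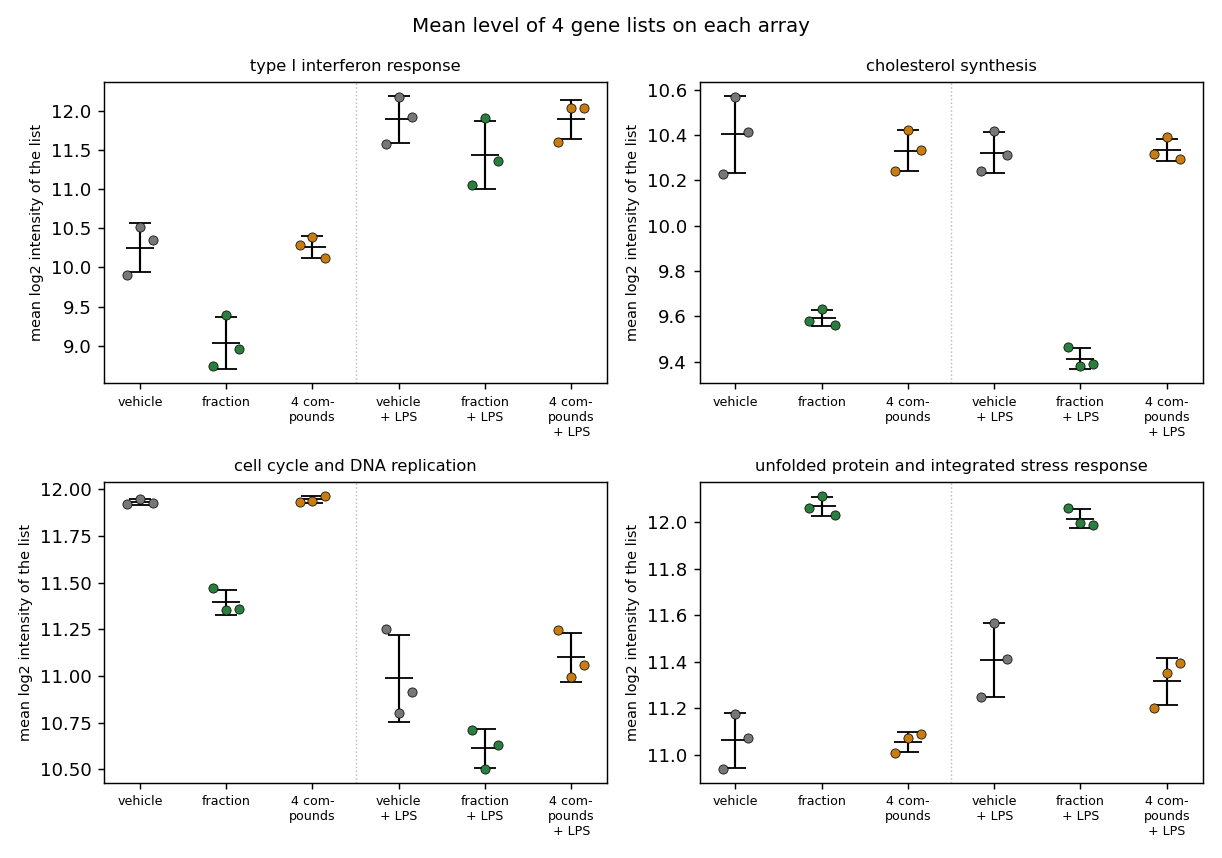
Mean log2 intensity of the members of 4 gene lists in the 6 groups, with a point for each array and the mean ± SD of n = 3 arrays. The cholesterol synthesis list was at 9.59 with the fraction and 10.33 with the mixture without LPS, and at 9.41 and 10.33 with LPS.

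The changes by fraction and mixture against vehicle were compared across the 11547 genes, with the same vehicle arrays as controls of both. The correlation was 0.225 without and 0.205 with LPS, where unchanged groups simulated against shared controls gave 0.502 and 0.499. The fraction effects had an SD of 0.574 without and 0.510 with LPS, against 0.310 and 0.336 for the mixture. Changes by the fraction that the mixture lacks lower the correlation, so it cannot be read against these simulations. The covariance was 0.0400 and 0.0352, against a simulated 0.0446 ± 0.0023 and 0.0440 ± 0.0020 (SD). It was thus not above what shared controls alone gave. With 0 genes called for the mixture (limma), the number of shared calls was 0 in either state.

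In fraction-treated cells, LPS raised Csf2 at least 114-fold, Il6 at least 202-fold, Il1b at least 206-fold and Lif at least 176-fold, and Ccl5 by 122-fold (6.93 ± 0.18, adjusted p = 1.6e-15, n = 3 per group). Klhl6, a gene of B-cell receptor signalling, fell 8.95-fold (-3.16 ± 0.20). In mixture-treated cells Il1b rose 180-fold (7.49 ± 0.21, adjusted p = 6.0e-15), Csf3 176-fold (7.46 ± 0.32), Ccl5 71.3-fold (6.16 ± 0.18) and Lif 62.7-fold (5.97 ± 0.22). E2f2, a transcription factor gene of the cell cycle, fell 6.08-fold (-2.60 ± 0.23). Ptgs2 rose 2.24 ± 0.17 in fraction-treated and 2.92 ± 0.17 in mixture-treated cells, Tnf 2.63 ± 0.13 and 1.97 ± 0.13, Nos2 2.31 ± 0.56 and 3.46 ± 0.56, and Socs3 6.12 ± 0.24 and 5.18 ± 0.24. Hmox1 was at -0.09 ± 0.14 (adjusted p = 0.67) and -0.26 ± 0.14 (0.20).

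LPS changed 4309 genes in fraction-treated cells (1330 higher, 2979 lower) and 2844 in mixture-treated cells (961 higher, 1883 lower). After median centring, which moved the median of all genes by 0.19 and 0.13, 60.4% and 60.7% of the called genes were higher. In fraction-treated cells 24 of 26 cytokines rose (25 over the list alone, adjusted p = 5.5e-29), 35 of 35 interferon response genes (35, 2.2e-32) and 22 of 27 feedback inhibitors (22, 4.3e-20). Of the heat shock genes there, 8 of 18 rose and 3 fell (10 and 3, 0.0021, 0.060 as an adjusted p with an estimated correlation). In mixture-treated cells 21 of 26 cytokines rose (23 over the list alone, adjusted p = 2.0e-30), 34 of 35 interferon response genes (34, 1.8e-27, 0.054 as an adjusted p with an estimated correlation) and 24 of 27 feedback inhibitors (25, 2.0e-30). Cell cycle genes fell in 30 of 34 and 31 of 34 cases (31 and 33 over the list alone, 4.2e-11 and 1.4e-18), with an adjusted p of 0.13 and 0.054 with an estimated correlation. The JAK-STAT list passed in mixture-treated cells (7 of 27 higher, 4 lower, 10 and 5 over the list alone, adjusted p = 0.047, 0.31 with an estimated correlation). After median centring 10 of its members were higher and 0 lower, and after quantile normalization 9 and 1. The list had a median of -0.01 against a mean of 0.23 and a test result of higher.

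Of the genes raised by LPS in vehicle-treated cells, 774 were also raised in mixture-treated cells (96.6 expected by chance) and 789 in fraction-treated cells (134 expected), and of those lowered 1620 (411 expected) and 1886 (650 expected). Opposite calls numbered 1 and 0 for the mixture and 13 and 7 for the fraction. These comparisons shared no arrays. The expected counts assume independent calls and may be too low, since the estimate of the spread per gene was shared.

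The fraction's effect differed between LPS-stimulated and unstimulated cells for 247 genes by an interaction test, 103 with a positive and 144 with a negative difference. The count was 467 with replicate number as a block, 125 without the intensity trend and 141 with only the compared arrays. Hspa1b had a difference of 2.99 ± 0.24 (adjusted p = 1.5e-06, n = 3 per group), with mean intensities of 987 in vehicle, 65.8 in fraction, 1727 in vehicle plus LPS and 912 in fraction plus LPS. Cxcl10 was at 2.35 ± 0.26 (adjusted p = 6.0e-05), with 4281, 617, 17053 and 12512 in the same order, and Klf4, a transcription factor gene, at -2.80 ± 0.28 (2.5e-05), with 133, 1630, 157 and 276. Lif was at 1.78 ± 0.31 (adjusted p = 0.0040) and Tyms, the thymidylate synthase gene, at 1.81 ± 0.36 (0.010, and 0.055 without the 6 arrays numbered 1, from 0.0042 over the alternatives). Tnf was at 1.01 ± 0.19 (0.0071), with means of 6457, 4125, 19820 and 25587. With the mixture arrays as controls in place of vehicle, Tnf was at 0.67 (adjusted p = 0.078), Sema7a at 2.54 (0.21), Sox4 at -0.15 (0.97) and Lims2 at -0.27 (0.90), against 4.204 ± 0.98, -3.58 ± 0.88 and -2.79 ± 0.67 for the last 3 with vehicle. These 3 genes had low signals, with means down to 14.2, 12.2 and 18.6, under the array medians, so the sizes of their differences are uncertain. Those 3 calls were also lost on leaving out single arrays, with adjusted p up to 0.082, 0.094 and 0.102. Over the alternatives the lowest adjusted p was 0.0020 for Tnf, 0.0032 for Sema7a, 0.0037 for Sox4 and 0.0040 for Lims2.

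Among lists, interferon response genes had 6 of 35 positive and 0 negative differences (14 over the list alone, camera adjusted p = 6.0e-15, 0.31 as an adjusted p with an estimated correlation). Ifit1 was at 1.58 ± 0.32, Mx2 at 1.69 ± 0.36 and Rsad2 at 1.63 ± 0.35. Without replicate 3 of vehicle Mx2 had an adjusted p of 0.057 (3.1e-04 to 0.065 over all alternatives). The unfolded protein and integrated stress response list had 6 of 23 negative (7 over the list alone, adjusted p = 0.0014, 0.36 with an estimated correlation). Ddit3 was at -2.10 ± 0.32, whose means were 292, 6275, 601 and 3011, and Trib3 at -1.44 ± 0.23. Prostaglandin and nitric oxide genes had 2 of 18 negative (2, 0.0014, 0.17 with an estimated correlation), with Ptger4 at -1.60 ± 0.19. Cytokines had 3 of 26 positive and 1 negative (5 and 1, 0.017, 0.41 with an estimated correlation). Cxcl2 was at -1.70 ± 0.28 and Ccl5 at 1.21 ± 0.26 (adjusted p = 0.019, 0.055 without replicate 3 of vehicle and 0.056 without replicate 2 of the fraction, 0.0093 to 0.144 over all alternatives).

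A further 6 lists passed with camera in this interaction with few called members, given here with the adjusted p and that with an estimated correlation. Positive were heat shock with 1 of 18 members (2 and 1 negative over the list alone, 0.0014, 0.17), extracellular matrix with 1 of 19 (3, 0.030, 0.31) and cell cycle with 2 of 34 (5 and 1 negative, 0.034, 0.76). Negative were alternative activation with 1 of 8 members (1 over the list alone, 0.030, 0.17), feedback inhibitors with 1 of 27 (5 and 1 positive, 0.043, 0.76) and lysosome with 0 of 21 (0, 0.0099, 0.41). Insig1, in the cholesterol synthesis list that did not pass, was at 1.26 ± 0.23 (adjusted p = 0.0064), and Fcgr2b at -1.84 ± 0.32 (0.0047). Ptgs2 was at -0.51 ± 0.25 (adjusted p = 0.37), Il1b at 0.44 ± 0.29 (0.56), Il6 at 0.22 ± 0.79 (0.95), Nos2 at -0.68 ± 0.79 (0.78), Socs3 at 0.98 ± 0.33 (0.16) and Hmox1 at -0.05 ± 0.20 (0.96). The count was 123 without replicate 2 of vehicle plus LPS, and without replicate 2 of the fraction group the called genes were 52.4% positive.

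For the mixture the same test called 0 genes with limma, with 412 (3.57%) at an unadjusted p < 0.05. The 5 genes with the smallest p did not pass: Klhl2 at 0.83 ± 0.15 (adjusted p = 0.311), Tnk1 at -2.89 ± 0.60 (0.755), and Lrrc8c at 1.16 ± 0.29, Zfp346 at -0.59 ± 0.15 and Sox4 at -3.43 ± 0.88 (0.999 for each). Il6 was at -1.43 ± 0.79, Tnf at 0.35 ± 0.19 and Ptgs2 at 0.18 ± 0.25, and Il1b, Nos2, Socs3 and Hmox1 were at 0.19, 0.47, 0.03 and -0.22 (0.999 for each). Tnk1, Sox4, Il6 and Nos2 lay under the array median in 1 or more groups. With camera 0 of the 21 lists passed, the lowest adjusted p being 0.055 for macrophage identity and for markers of other cell types, and for 73.5% of genes the 95% confidence interval lay within 2-fold. Without replicate 1 of vehicle plus LPS, 10 genes passed with limma and 9 lists with camera.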

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

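The test of a signal ceiling and the regroupings of the arrays for the 11 comparisons were planned before their results were seen, and all other tests in this part were chosen after the result was seen. The test of RNA degradation on the actin ratio took the place of an earlier one on the Gapdh ratio. The earlier one had left that explanation open because the Gapdh ratio was lower with the fraction than with vehicle by more than 2 standard errors.

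The fraction's effect differed between cells with and without LPS, by a test of the difference itself, for 247 genes, and the 5 genes chosen by rule in each direction are singled out for that reason. Sema7a was at 4.204, Hspa1b at 2.99, Cxcl10 at 2.35, Tyms at 1.81 and Lif at 1.78 (log2), against Sox4 at -3.58, Slc46a3 at -2.84, Klf4 at -2.80, Lims2 at -2.79 and Col4a1 at -2.75. Tnf, 1 of the genes followed throughout, was at 1.01. Sema7a, Sox4, Slc46a3, Lims2, Lif and Col4a1 had means down to 14.2, 12.2, 24.5, 18.6, 49.0 and 55.3, under the array medians, so the sizes of their differences rest on low signals. With the mixture arrays as controls Sema7a was at 2.54 (adjusted p = 0.21), Sox4 at -0.15 (0.97), Lims2 at -0.27 (0.90) and Tnf at 0.67 (0.078), and these 4 calls were lost. The 12 arrays allow 200 distinct regroupings of this kind, of which 100 were drawn: 12 of them gave at least 247 genes, the highest other count being 4653. Regroupings that swap treatments within an LPS state carry the fraction's average effect, so a count this far above the real one points to the structure of the samples. With that average effect removed, a version added after the first was seen, 1 of 100 gave as many, the real grouping with 237 genes. The highest other had 61. The removed effect was estimated from the real grouping, which can lower the other counts and leaves the real difference as it was. This version therefore cannot exclude chance, which the planned version left open. For the mixture the real count was 0 genes, which 100 of 100 regroupings reach by construction, the highest other being 29, so this count decides nothing.

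Probe sets that carried no single gene name were not used in the comparisons, and many of the 4059 tested passed the threshold. They numbered 435 for LPS in vehicle cells, 605 in fraction-treated and 341 in mixture-treated cells, 532 for the fraction without LPS and 370 with LPS, 498 and 406 for fraction against mixture without and with LPS, and 5 for the fraction interaction. With limma 0 passed in the 3 comparisons of the mixture with vehicle, its interaction included.

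In the first pattern weighed, the mean fall of 35 interferon response genes with the fraction was smaller in LPS-stimulated than in unstimulated cells. The mean changes were -0.45 ± 0.31 and -1.23 ± 0.26 (log2 ± SE from the spread between arrays), a difference of 0.77 ± 0.40. That difference lay within 2 standard errors of 0, and the list did not pass this interaction with an estimated correlation. The SEs treat the arrays as unpaired. Yet in vehicle and fraction, with and without LPS, the list was lowest on replicate 1 and highest on replicate 2. The SEs therefore include any shift shared by a replicate number and may be too wide for this difference. It was not computed within replicate numbers. The difference was 0.78 ± 0.36 against the mixture arrays and 0.82 ± 0.40 after quantile normalization, each narrowly over 2 standard errors. Since the pattern itself did not pass that mark, these values argue only weakly against vehicle arrays alone or scaling as the whole cause. A ceiling of the signal in LPS-stimulated cells stays open: the 17 dimmer members had a difference of 0.66 ± 0.45, within 2 standard errors of 0, and the brighter 18 one of 0.88 ± 0.37. With these unpaired SEs that test has little power, since the whole list also lies within 2 standard errors of 0. A biological explanation by the LPS state, which the design names, also stays open and may hold together with a ceiling.

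In the second pattern, genes raised by LPS had a lower mean with the mixture plus LPS than with vehicle plus LPS (-0.18 ± 0.15). This difference lay within 2 standard errors of 0, and 0 of the 436 genes passed the threshold. In vehicle plus LPS, replicate 1 was lowest, at 9.25 against 9.72 and 9.65 for the others. Replicate 1 was also lowest in vehicle without LPS (7.63 against 7.88 and 7.90). The same held in the mixture plus LPS (9.26 against 9.39 and 9.43). Without replicate 1 of vehicle plus LPS the difference was -0.33 ± 0.072. This decides nothing about the part of that array, since leaving out the lowest vehicle array can only make the difference more negative. Spread between the arrays of a group stays open, with an exact two-sided permutation p of 0.4 for 3 arrays against 3. An effect of the mixture on the LPS response may also account for it and stays open.

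The third pattern is the number of genes changed by the fraction without LPS, 3608, for which scaling is argued against, since 3656 genes passed after quantile normalization. Hybridization differences are argued against only weakly. The spike-in controls shifted by 0.29 ± 0.17 in the mixture arrays, where 0 genes passed with limma (565 at an unadjusted p < 0.05). In the fraction arrays they shifted by 0.22 ± 0.15, and both shifts lay within 2 standard errors of 0. With LPS the mixture arrays shifted by 0.35 ± 0.11, again with 0 genes past the threshold (934 unadjusted). The actin 3' to 5' ratio was higher than in vehicle by 0.061 ± 0.019 with the mixture and by 0.054 ± 0.036 with the fraction. The Gapdh ratio moved the other way, by -0.019 ± 0.012 with the mixture and -0.021 ± 0.0093 with the fraction. The actin ratio was chosen after the Gapdh ratio had left RNA degradation open, and its shift with the fraction lay within 2 standard errors. RNA degradation therefore stays open. The Gapdh ratio did not rise with the fraction, however, and the mixture arrays had an actin rise with 0 genes past the threshold. An effect of the fraction itself, which the design names, may account for the count, as a hypothesis from the same data.

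The other counts rest on 3 arrays against 3, where 10 groupings are too few for a share under 0.05. As many genes as in the real grouping came from 1 of 10 for LPS in vehicle cells (3680, highest other 0), for LPS in fraction-treated (4309, 0) and mixture-treated cells (2844, 0), for the fraction without LPS (3608, 2) and with LPS (2746, 2), and for fraction against mixture without LPS (3743, 1) and with LPS (3255, 1). For the mixture the real count was 0, which 10 of 10 reach by construction, the highest other being 4 without LPS and 17 with LPS.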

How the results depend on the processing

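The alternatives that left out the 6 arrays numbered 1, took the mixture arrays as controls of the fraction interaction, or set signals to at least the array median were chosen after the result was seen. The cause of the changes below was not tested, except that a minimum change of 1.5-fold and fewer arrays or genes lower counts by construction. Of the named gene results under all alternatives, 18382 kept their direction and side of the threshold, 142 passed newly, 742 no longer passed and 1 reversed, a change of sign being counted where the reported or the alternative value passed. Of the list results 2758 kept both, 105 passed newly, 147 no longer passed and 3 reversed. Of 664 called named gene results, 54 were lost without the intensity trend, 52 with only the compared arrays and 80 without the arrays numbered 1. Of 39 called results of the fraction interaction, 12 were lost with the mixture arrays as controls. Low signal limits some calls: with signals set to at least the array median 47 of 655 were lost, and Trim30d, Lrfn4, Vamp5, Clec2d and Gbp2 had no value in comparisons where every array was at that floor. The dependence of directions of the LPS response on scaling is described with that response.

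After removing group means, all 45 pairs of arrays with the same replicate number correlated positively, from 0.018 to 0.170 with a median of 0.088 and 9 of them over 0.1, against a median of -0.037 for other pairs. Removing group means itself pushes other pairs below 0 when same-number pairs are positive. Of the 18 arrays, 10 correlated best with their own number in every other group. The data thus show that the numbers share something, although the labels do not state what. The main fit does not account for this, and the replicate block was used as an alternative. With the block, 467 genes passed for the fraction interaction against 247, and 4169 for LPS in vehicle cells against 3680.

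With a minimum of 1.5-fold, 1884 genes passed for LPS in vehicle, 2325 in fraction-treated and 1441 in mixture-treated cells, 1637 for the fraction without and 1163 with LPS, and 1737 and 1446 for fraction against mixture without and with LPS. For the mixture without LPS, 1 gene passed with no filter and 5 without the arrays numbered 1. With LPS, 1 passed with a replicate block, 1 after median centring, 2 with every probe set and 63 without the arrays numbered 1. For the fraction interaction 467 passed with the replicate block, 125 without the intensity trend and 141 with only the compared arrays, and for the mixture interaction 2 without the arrays numbered 1.

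With an estimated correlation, lists past the threshold numbered 5 for LPS in vehicle, 6 in fraction-treated and 5 in mixture-treated cells, 1 for the fraction with LPS, and 0 for the fraction without LPS, the mixture without and with LPS, both comparisons of fraction with mixture and the fraction interaction. With fry 0 passed for the mixture without and 0 with LPS, and 3 for the fraction interaction. After quantile normalization 0 passed for the mixture without LPS and 1 for its interaction. With the 75th percentile filter 2 passed for the mixture without LPS, 5 for fraction against mixture without LPS and 1 for the mixture interaction. Without the arrays numbered 1 they were 6 for the mixture without LPS, 8 with LPS and 2 for its interaction.

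The mean change of LPS-raised genes under the fraction was 0.15 (p = 0.547 with an estimated correlation, 0.227 with fry) and 0.033 without the arrays numbered 1. For LPS-lowered genes it was -0.12 (0.398 and 0.053) and -0.0088. Under the mixture it was -0.18 for raised (0.142 and 0.238) and 0.094 for lowered genes (0.187 and 0.081). The correlation of fraction and mixture effects was 0.1504 without and 0.088 with LPS on log2 of the value plus 32, and 0.083 and, reversed, -0.099 with the 75th percentile filter. Also reversed were Kcnd1 in fraction against mixture without LPS (0.0038 with signals set to at least the array median), alternative activation for LPS in fraction-treated cells (a median of 0.417 where fry tested lower), and the interferon list for the mixture without LPS (-0.126 without the arrays numbered 1, -0.176 without replicate 1 of vehicle). LPS-raised genes under the fraction were at -0.010 without replicate 1 of vehicle plus LPS.

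Leaving out each array in turn gave these ranges of genes past the threshold: 2805 to 3800, 3603 to 3876 and 2086 to 2519 for LPS in vehicle, fraction-treated and mixture-treated cells, 2900 to 3224 and 2087 to 2501 for the fraction without and with LPS, 3039 to 3298 and 2570 to 2776 for fraction against mixture, and 123 to 344 for the fraction interaction. For the mixture they were 0 to 3 without LPS (3 without its replicate 1), 0 to 191 with LPS and 0 to 10 for the interaction, both highest without replicate 1 of vehicle plus LPS. Lists past the threshold ranged in the same order over 11 to 13, 10 to 11, 10 to 12, 7 to 10, 5 to 6, 7 to 10, 6 to 7 and 6 to 11 (6 without replicate 1 of vehicle). For the mixture they ranged over 0 to 6 without LPS (6 without replicate 2 of vehicle), 0 to 10 with LPS and 0 to 9 for the interaction, with 10 and 9 without replicate 1 of vehicle plus LPS and 0 without its replicate 3 for the first. The means of LPS-raised and LPS-lowered genes ranged over -0.010 to 0.258 and -0.196 to -0.012 under the fraction, and over -0.327 to -0.092 and 0.052 to 0.173 under the mixture. The correlation ranged over 0.175 to 0.341 without and 0.182 to 0.328 with LPS.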

Other observations

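The lists and tests in this part were all chosen after the result was seen. Without LPS, the fraction raised genes of amino acid supply and of the charging of transfer RNA. Of the cytosolic aminoacyl-tRNA synthetase genes, 12 of 19 rose and 0 fell (13 over the list alone, camera adjusted p = 1.5e-10, 0.0023 with an estimated correlation), with Aars at 1.34 ± 0.091 and Cars at 1.14 ± 0.085 (n = 3 per group). Of the amino acid transporter genes, 11 of 16 rose and 1 fell (12 and 1 over the list alone, 1.8e-07, 0.0066 with an estimated correlation), with Slc1a4 at 3.38 ± 0.18. Of the serine, one-carbon and cysteine pathway genes, 9 of 13 rose and 2 fell, also over the list alone (6.2e-06, 0.021 with an estimated correlation), with Cth at 3.10 ± 0.14 and Mthfd2 at 1.32 ± 0.086. Of the mitochondrial synthetase genes 1 of 16 rose and 1 fell (0.68). With LPS these 3 lists also rose, with 13 of 19, 9 of 16 and 9 of 13 members higher (camera adjusted p = 3.8e-14, 3.5e-09 and 1.6e-09).

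Ribosome biogenesis genes had 10 of 25 lower and 2 higher with the fraction without LPS, also over the list alone (camera adjusted p = 0.0061, 0.15 with an estimated correlation), with Nop16 at -0.76 ± 0.068. Iron handling genes had 6 of 14 higher and 3 lower (0.19) and complex I genes 1 of 28 higher and 6 lower (0.32). Of 26 ribosomal protein genes, 0 passed over all genes with the mixture without LPS (limma), while 20 were higher and 2 lower adjusted over the list alone (camera adjusted p = 2.6e-18, 0.20 with an estimated correlation). In the same arrays the actin 3' to 5' ratio was 0.061 ± 0.019 and the spike-in signal 0.29 ± 0.17 (log2) above vehicle.

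A hypothesis from these values is that the fraction evokes an amino acid response, in which the transcription factor ATF4 raises cytosolic but not mitochondrial synthetase genes. The mean change of cytosolic minus mitochondrial synthetases was 0.52 ± 0.042 without and 0.51 ± 0.068 with LPS. This restates the difference that gave rise to the hypothesis, so it decides nothing about it, and ATF4 activity was not measured.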
